A study of Mus musculus with 8 samples.

How the data were processed

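RNA was taken from 4 replicates of NS5 neural stem cells and 4 replicates of NS5-derived astrocytes, and the label protocol calls the 4 of each cell type biological replicates. Per the labels' protocols, cells were lysed in TRIzol, the RNA was cleaned on RNeasy columns, amplified with the Illumina TotalPrep kit and labelled with biotin. The platform of the probe annotation is the Illumina MouseRef-8 v1.1 bead array, with 1 colour and 1 sample per array. No slide, chip or scan date was given in the sources used here, so a batch of that kind could not be tested, and it stays open whether groups and slides were arranged together.

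The scanner-level table deposited by the authors holds linear probe intensities, with no detection p-value and with negative values, from which it follows that a background had already been subtracted. The scanner software, background method and filters are not given in the sources used here. Between 29.6% and 30.7% of the intensities on an array were 0 or below. The authors also deposited a value table of log2 values. Compared with the intensities of the same samples, these log2 values equal the intensities with values under 10 set to 10, log2 transformed and quantile normalized, within 4.99e-09. They were not centred, and the median of each column was 4.93. Over probes with an intensity above 50, the rank correlation of each intensity column with its own column of that table was 1, and at most 0.987 with another column. The value table served as an alternative only.

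Of 24613 probes, 1 further row being empty, 20984 had 1 gene symbol in the platform annotation, 1 had several and 3628 were not listed there. Of the latter, 687 were named through the accession in the intensity table and a RefSeq gene table (GRCm38.p6), which was used for names alone, and 2942 probes stayed unnamed and stood for themselves, including the probe with several symbols. No genome build is given with the files, so coordinates are not printed. In total 16449 symbols were present.

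The design fixed before the data were examined assumed signals with a detection p and limma's neqc. Because the signals had no detection p and were already background-subtracted, the fallback written in the same design was used. Each intensity was raised by 99.01, which set the lowest value to 16, log2 transformed and quantile normalized between arrays. Probes with a mean log2 above the median of all probes were kept (12306), and for each symbol the probe with the highest mean was used, giving 10377 genes. Where another probe of a named gene also passed the filter, it had the same sign for each gene named here, and the sizes that differed stand beside Sox2, Rrm2, Ccnd1, Dusp6, Ccn1, Fn1 and Gad1. By the other probe, Cd109 had a log2 fold change of 1.62, Map2 -0.78 and Srm -2.82, the last with 2 of the 4 astrocyte arrays above background, while Ccnb1 was at least 19.0-fold, Tk1 at least 10.6-fold and Dcpp1 at least 47.5-fold lower. Further probes that did not pass the filter were not above background on any array for Nes, Plk1, Trib3, Map2, Dlx2 and Cd109, and on at most 1 array of a group for Tk1, Fn1, Egfl7 and Klf4. Fold changes are astrocyte minus NS5 on the log2(signal + 99.01) scale, which understates the change of dim genes. Signals in the text are the normalized values after removal of that offset, in scanner units, as mean ± SD over the 4 arrays of a group. With no detection p, a background limit per array was set, after the files had been seen, at 1.645 times the root mean square of the negative signals, which gave 35.4 to 39.8 units. A gene not above this limit on any array of a group has only a bound there, computed as the mean normalized log2 value of the bright group against the mean over the dim group of the higher of, per array, the lowest normalized value among probes above the limit and the dim probe's own value.

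Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single term, all 8 arrays), with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit. The p-values measure the spread between these replicate cultures of 1 cell line. Gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists, and beside it with camera with an estimated correlation and with fry. A list needed 5 measured members. The 22 lists, fixed beforehand, were astrocyte markers, neural stem and radial glia markers, mitosis, DNA replication, cell cycle exit, ERK feedback and growth factor response, actin cytoskeleton and serum response factor targets, BMP signalling targets, cytokine and STAT3 signalling, reactive astrocyte genes, cholesterol synthesis, extracellular matrix, interferon and MHC class I, Notch signalling, ribosome biogenesis and MYC targets, stress response, and markers of neurons, the oligodendrocyte lineage, microglia and macrophages, fibroblasts and pericytes, endothelium and pluripotency. They held 439 genes, of which 405 were on the array and 270 were measured above the filter.

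The genes named in the text followed a rule fixed beforehand: Gfap, S100b, Nes, Sox2 and Mki67, the 10 called genes with the highest and the 10 with the lowest log2 fold change whose groups did not overlap and which have a gene symbol other than a clone name, and from each list the up to 4 called members with the largest change. Some genes that this rule takes are not reported here. The procedure was tested on simulated arrays, 4 against 4 over 10350 genes. Both simulated groups had the NS5 means and the pooled real spreads, apart from the changed genes. It recovered 65.0% of 60 genes changed by 0.5 on the log2 scale, 96.4% of 56 changed by 1 and 100% of 52 changed by 2, and called 7 of 10182 unchanged genes. Of 10 simulated lists shifted by 0.5, 10 were called, and 0 of 10 lists without a shift. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.30. The simulation therefore does not show how often camera with the preset correlation calls a real list falsely. Few simulated genes were changed, whereas 59.2% of the genes tested were called in the real data. The shares of recovered and falsely called genes therefore do not carry over to the real comparison. Nor was quantile normalization tried with so many changed genes.

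The alternatives tried were quantile normalization without an added offset, median centring, the authors' value table, no filter, a filter at the 75th percentile, the mean of all probes of a gene, all probes, a trend and robust prior, array weights, the replicate number as a block, an estimated correlation and leaving out each array in turn, and, chosen after the data had been seen, an offset of 16 with negative signals at 0 and a filter on the background limit. In the first of these, values below the lowest positive signal were raised to that signal, called the positive floor below. No setting, the main one included, subtracted a further background.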

Results

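Gene expression was measured on 8 Illumina mouse bead arrays, 4 hybridised with RNA from NS5 cells and 4 with RNA from astrocytes derived from them. NS5 is a mouse neural stem cell line that divides as an adherent culture when supplied with growth factors. The astrocytes were obtained by withdrawing the growth factors and adding 5% fetal calf serum for 3 days, a procedure that the labels describe as giving GFAP-positive cells. The comparison asked which transcripts differ between the stem cells and the cells derived from them. Each array held 24613 probes, with a median signal between 28.0 and 33.0 and a mean signal between 469 and 648 units. Between 46.0% and 47.9% of the probes on an array exceeded an estimated background limit. The precision of the values is limited by the 4 arrays in each group.

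The genes with the highest fold changes in astrocytes included genes of small chaperones, a metallothionein, secreted acute-phase and complement proteins and a water channel, and those with the lowest included genes of cell division and of histones. Of 10377 genes tested, 6138 (59.2%) were called at an adjusted p under 0.05 with limma, 3025 of them higher and 3113 lower in astrocytes. The change was at least 2-fold for 1924 called genes (18.5% of those tested), with 1023 higher and 901 lower, and at least 4-fold for 318 higher and 222 lower genes. With median centring in place of quantile normalization the majority turned, with 935 higher and 1020 lower at 2-fold or more. The number of 2-fold changes depends on the scaling, with 2904 in the authors' value table and 2645 with the offset of 16. The 4 signals of one group all lay above the 4 of the other for 5696 genes (54.9%), against 2.86% expected by chance. Within groups, arrays correlated at 0.993 to 0.995 for NS5 cells and 0.984 to 0.994 for astrocytes across genes, which are not independent replicates, and between groups at 0.848 to 0.859. The first principal component carried 92.0% of the variance and the second 2.72%. Among called genes, 307 were higher in astrocytes and not above background on any NS5 array, and 184 were lower and not above background on any astrocyte array. These counts go by the probe used for each gene, and for such genes only a lower bound of the fold is given ("at least").

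Gfap, the intermediate filament gene of astrocytes (probe ILMN_1214715), was not above background in NS5 cells, with a signal of -11.5 ± 6.01 (SD, n = 4), and reached 2320 ± 944 in astrocytes, at least 16.7-fold higher (adjusted p = 4.87e-10). Of the 21 measured astrocyte markers, 15 rose and 1 fell, with a median log2 fold change of 1.18, and 16 rose and 1 fell when adjusted over the list alone. Of the 23 markers on the array, Slc1a2 was not above background on any array and is not counted. Besides Gfap, the largest increases were those of Clu, a secreted chaperone also called apolipoprotein J, with a log2 fold change of 5.79 ± 0.15 (SE), of the water channel Aqp4, at least 36.6-fold higher, and of Atp1b2, a sodium pump subunit, with 5.15 ± 0.10. S100b, a calcium-binding protein used as an astrocyte marker (probe ILMN_2634742), did not pass the test, with a signal of 625 ± 135 in NS5 cells and 839 ± 243 in astrocytes and a log2 fold change of 0.35 ± 0.19 (adjusted p = 0.135). Without astrocyte array 1 it passed, at 0.55 (adjusted p = 0.00334), and it also passed with array weights, at 0.39 (adjusted p = 0.0399), while its adjusted p ran from 0.00334 to 0.358 over 19 alternatives. The marker list was called by camera (adjusted p = 9.84e-07), with an adjusted p = 0.102 with an estimated correlation.

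**Figure D1:**
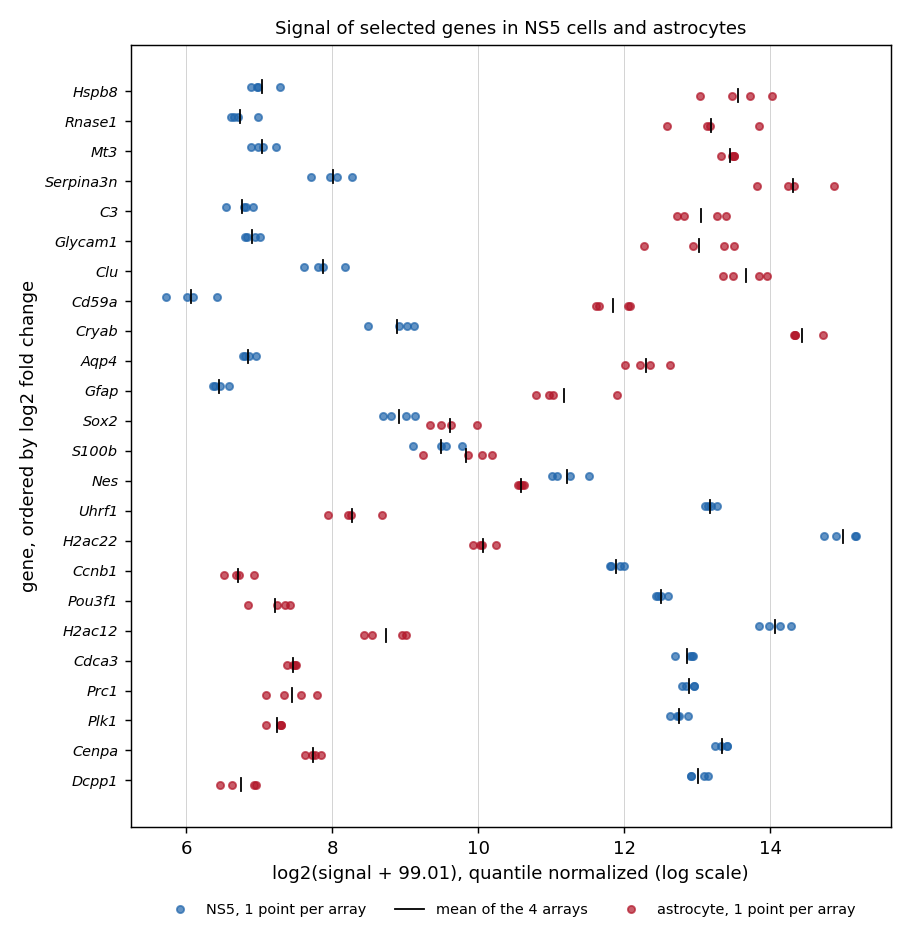
Log2 signal on each array, quantile normalized after adding 99.01 (horizontal axis, log scale), for the 10 genes with the highest and the 10 with the lowest fold change and for Gfap, S100b, Nes and Sox2 (vertical axis). Blue points are the 4 NS5 arrays, red points the 4 astrocyte arrays and black bars the group means. The groups were apart for each gene except S100b, whose log2 fold change was 0.35 ± 0.19 (SE).

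The 10 genes with the highest fold changes included Hspb8 and Cryab, both small heat shock proteins. Hspb8 went from a signal of 32.4 ± 17.0 (SD, n = 4), above background on 1 of the 4 NS5 arrays, to 12354 ± 3475, a log2 fold change of 6.53 ± 0.17 (SE). Cryab rose from 379 ± 84.7 to 22163 ± 3135. Mt3, a metallothionein of brain, was above background on 1 of the 4 NS5 arrays and had a log2 fold change of 6.42 ± 0.09. The secreted protease inhibitor Serpina3n rose from 160 ± 42.1 to 20984 ± 6530, and the complement component C3 was at least 61.7-fold higher, with 8557 ± 1983 in astrocytes. Rnase1, a secreted ribonuclease, was at least 67.6-fold higher, the mucin-like Glycam1 at least 60.3-fold higher, and Cd59a, a cell-surface inhibitor of complement, at least 26.7-fold higher. Clu and Aqp4 completed this set. Cd59a and Serpina3n have close relatives in the mouse genome, and how far their probes tell them apart was not tested.

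Genes of mitosis fell, and all 21 measured members were lower in astrocytes, with a median log2 fold change of -3.48. Cenpa, the histone variant of centromeres, had a log2 fold change of -5.60 ± 0.08 (SE) and a signal of 10289 ± 571 (SD, n = 4) in NS5 cells against 115 ± 12.8 in astrocytes. Plk1, a mitotic kinase, had -5.50 ± 0.08, and Prc1, which bundles spindle microtubules, -5.44 ± 0.13. Ccnb1, the mitotic cyclin B1, was not above background on any astrocyte array and was at least 28.1-fold lower. The smallest fall of the list was that of Hmmr, at -0.27, a gene chosen after its values were seen. All 30 measured genes of DNA replication fell as well, with a median of -2.22. Uhrf1, which maintains DNA methylation at replication, had -4.90 ± 0.13, and Mcm5, a subunit of the replicative helicase, -4.29 ± 0.09, while Tk1, thymidine kinase, was at least 13.0-fold lower. Rrm2, a subunit of ribonucleotide reductase, was at least 10.8-fold lower by its brighter probe and at least 1.61-fold lower by another. Camera gave an adjusted p = 2.09e-15 for mitosis and 1.95e-18 for replication, and both lists were also called with an estimated correlation (adjusted p = 0.0240 and 0.0365). No probe was named as Mki67, which is not analysed here.

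The other genes with the lowest fold changes were not members of those lists. Dcpp1, a secreted salivary-type protein, was at least 61.2-fold lower, from a signal of 8186 ± 684 (SD, n = 4) in NS5 cells to below background. The cell division gene Cdca3 had a log2 fold change of -5.40 ± 0.08 (SE). Pou3f1, a POU-domain transcription factor, had -5.28 ± 0.11 and was above background on 3 of the 4 astrocyte arrays. The histone genes H2ac12 and H2ac22 had -5.33 ± 0.14 and -4.93 ± 0.11. Dcpp1 and the H2ac genes belong to families of nearly identical sequence, and how far their probes tell the copies apart was not tested.

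Genes of cell cycle exit moved both ways, 6 up and 5 down of 13 measured, with a median log2 fold change of 0.06, and the list was not called (adjusted p = 0.748). The growth arrest gene Gadd45g had a log2 fold change of 3.06 ± 0.21 (SE), and its relatives Gadd45a and Gadd45b rose by 1.89 ± 0.12 and at least 3.81-fold. Cdkn2b, an inhibitor of cyclin-dependent kinases, rose by 2.08 ± 0.13 on the log2 scale. Cdkn1a, another such inhibitor, fell by 1.25 on that scale and was chosen after its values were seen.

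Neural stem and radial glia markers did not move together. Of 17 measured, 6 rose and 6 fell, with a median log2 fold change of 0.02, and the list was not called (adjusted p = 0.931). Nes, an intermediate filament of neural progenitors (probe ILMN_2703267), fell from a signal of 2299 ± 395 (SD, n = 4) to 1441 ± 36.3, a log2 fold change of -0.63 ± 0.10 (SE, adjusted p = 1.79e-04). Sox2, a transcription factor of neural stem cells (probe ILMN_1248711), rose from 385 ± 66.1 to 692 ± 155, a log2 fold change of 0.70 ± 0.13 (adjusted p = 5.90e-04), and by 0.47 on its other probe. Prom1, the membrane protein prominin, was at least 3.16-fold higher. Sox11 had -1.73 ± 0.08, the Notch ligand Dll1 -0.90 ± 0.09, and Olig2, a transcription factor of progenitors and the oligodendrocyte lineage, was at least 2.49-fold lower. The median and mean of this list lay above 0, while the direction of its test was down.

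Genes that respond to growth factor signalling through ERK fell for the most part. Of 16 measured, 11 fell and 2 rose, with a median log2 fold change of -1.14. Ccnd1, cyclin D1, fell from a signal of 24810 ± 2650 (SD, n = 4) to 808 ± 335, a log2 fold change of -4.84 ± 0.20 (SE), and its other probes had -3.61 to -4.64, 2 of them above background on 3 of the 4 astrocyte arrays. Etv5, an ETS transcription factor, had -4.45 ± 0.22 and was above background on 2 of the 4 astrocyte arrays. Dusp6, a phosphatase of ERK, had -3.86 ± 0.19, against -1.93 by another probe, which was above background on 1 of the 4 astrocyte arrays. Fos, an immediate-early transcription factor, went the other way, with 3.83 ± 0.69 and signals of 305 ± 349 and 6176 ± 5627, so that its spread was near its mean in both groups. Camera called the list (adjusted p = 1.11e-03), with an adjusted p = 0.225 with an estimated correlation.

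Targets of BMP signalling were higher: 4 of 6 measured rose and 0 fell, with a median log2 fold change of 1.55. Id1, Id3 and Id2, inhibitors of basic helix-loop-helix factors, had 3.22 ± 0.09, 1.62 ± 0.08 and 1.47 ± 0.11 (SE), and the transcription factor Hey1 had 2.93 ± 0.17. The list was called by camera (adjusted p = 6.46e-03), with an adjusted p = 0.102 with an estimated correlation. In the Notch list, which shares Hey1, 4 of 9 measured genes rose and 3 fell, with a median of 0.11, and the list was not called (adjusted p = 0.820). The receptor Notch3 had 1.37 ± 0.11, the feedback regulator Nrarp -1.09 ± 0.11, and the ligand Jag1 was at least 2.42-fold lower.

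Genes of cytokine and STAT3 signalling rose in 8 of 11 cases and fell in 3, with a median log2 fold change of 1.33. Il6st, the shared receptor subunit gp130, was at least 13.3-fold higher, with a signal of 1737 ± 48.8 (SD, n = 4) in astrocytes. Socs3, a feedback inhibitor of this pathway, had a log2 fold change of 3.92 ± 0.46 (SE) with a wide spread between astrocyte arrays, 2517 ± 2139, and was above background on 1 of the 4 NS5 arrays. Junb had 2.75 ± 0.23 and was above background on 3 of the 4 NS5 arrays, and the transcription factor Cebpb had 2.14 ± 0.16. Reactive astrocyte genes rose in 10 of 16 cases and fell in 1, with a median of 1.05. Besides Serpina3n, Lcn2, an iron-siderophore carrier of the acute phase, was at least 18.2-fold higher, the copper carrier Cp at least 5.33-fold higher, and Cd109 had 2.06 ± 0.12. Both lists were called by camera (adjusted p = 0.0171 and 3.29e-04), with an adjusted p = 0.102 and 0.129 with an estimated correlation. Of 12 microglia and macrophage markers on the array, 0 were measured above the filter, and their signals in astrocytes had a median of -0.21 against a background limit of 36.7.

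Of 11 interferon and MHC class I genes, 8 rose and 0 fell, with a median log2 fold change of 0.69. Ifitm3, an interferon-induced membrane protein, had 3.68 ± 0.15 (SE), the peptide transporter Tap2 1.97 ± 0.09, and Irf9 1.69 ± 0.11 with 2 of the 4 NS5 arrays above background. The list was called by camera (adjusted p = 5.27e-03), with an adjusted p = 0.102 with an estimated correlation. It had 18 members on the array. Of these, H2-K1, H2-D1, Ifit1, Oasl2 and Bst2 were not above background on any array and are not counted. The count therefore does not cover the whole list. In the stress response list 3 of 12 genes rose and 4 fell, with a median of 0.17, and the list was not called (adjusted p = 0.820). Hmox1, heme oxygenase, had 2.58 ± 0.18 and Ddit3 0.91 ± 0.11, Atf3 was at least 2.01-fold higher, and Trib3 had -0.84 ± 0.09.

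Enzymes and regulators of cholesterol synthesis fell in 19 of 21 measured cases and rose in 1, with a median log2 fold change of -1.80. Fdft1, named after its values were seen, did not pass the filter and is not counted. Its signal was -13.0 ± 17.2 (SD, n = 4) in NS5 cells and 63.1 ± 11.3 in astrocytes, above background on the 4 astrocyte arrays alone. Fdps, farnesyl diphosphate synthase, fell from a signal of 10260 ± 1184 (SD, n = 4) to 1065 ± 92.8, a log2 fold change of -3.15 ± 0.10 (SE). Lss, lanosterol synthase, had -2.84 ± 0.12, Acat2 -2.71 ± 0.09 and Cyp51 -2.64 ± 0.10. All 14 measured genes of ribosome biogenesis and MYC targets fell, with a median of -1.52. Srm, spermidine synthase, had -2.77 ± 0.10, and the nucleolar proteins Fbl, Ppan and Nop56 had -2.22 ± 0.07, -2.21 ± 0.18 and -1.89 ± 0.10. Camera called both lists (adjusted p = 1.02e-08 and 1.60e-07), each with an adjusted p = 0.102 with an estimated correlation.

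Of 9 genes of the actin cytoskeleton and serum response factor targets, 7 rose and 1 fell, with a median log2 fold change of 0.37. The matricellular Ccn1 was at least 4.10-fold higher, or at least 2.26-fold by another probe, smooth muscle actin Acta2 at least 2.22-fold higher by 1 probe, its others not being above background on any array, and the adhesion and actin-binding genes Vcl and Flna had 1.09 ± 0.10 and 0.85 ± 0.08 (SE). Of the 17 list members on the array, Tagln, Tagln2, Cnn1, Ccn2 and Ankrd1 were not above background on any array and are not counted. Camera called this list (adjusted p = 0.0357), with an adjusted p = 0.398 with an estimated correlation. The call was lost without astrocyte array 1 (median 0.29, adjusted p = 0.131), without astrocyte array 2 (median 0.40, adjusted p = 0.0635) and under 4 other settings, with an adjusted p between 0.0237 and 0.268 over 19 alternatives. Extracellular matrix genes rose in 7 of 14 cases and fell in 3, with a median of 0.34, and were not called (adjusted p = 0.0702, or 0.157 with an estimated correlation). They were called under 2 other settings, with medians of 1.97 and 0.34, and over 19 alternatives the median ran from 0.08 to 2.11 and the adjusted p from 0.0282 to 0.131. Timp2, an inhibitor of metalloproteinases, rose from a signal of 714 ± 41.1 (SD, n = 4) to 14247 ± 550, a log2 fold change of 4.14 ± 0.07. Fibronectin, Fn1, had 2.90 ± 0.11, against 2.03 by another probe with 1 of the 4 NS5 arrays above background, Col5a1 2.11 ± 0.15, and Sparc was at least 3.77-fold higher.

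Markers of other cell types gave no list that passed the test. Neuron markers rose in 2 of 11 cases and fell in 3, with a median log2 fold change of -0.04 (adjusted p = 0.748). Gap43 was at least 1.84-fold higher, Map2 had -0.96 ± 0.08 (SE), Dlx2 -0.40 ± 0.09 with 1 of the 4 astrocyte arrays above background, and Gad1 0.61 ± 0.19, against 0.07 by another probe. Gad1 was not called with median centring, at 0.55 (adjusted p = 0.0560), the highest of 19 alternatives, whose lowest adjusted p was 0.00646, and its value fell to 0.38 without astrocyte array 1 and to 0.34 with the mean of all probes. Oligodendrocyte lineage markers rose in 4 of 10 cases and fell in 4, with a median of -0.02 (adjusted p = 0.748). The transcription factors Sox8 and Olig1 had -3.18 ± 0.19 and -1.53 ± 0.12. Of 5 fibroblast and pericyte markers, 1 rose and 0 fell, with a median of -0.02 (adjusted p = 0.623), and the riser was S100a4, a calcium-binding protein, with 2.87 ± 0.12. Of 5 measured pluripotency markers, 1 rose and 2 fell, with a median of -0.05 (adjusted p = 0.820). Nanog, named after its values were seen, did not pass the filter and is not counted. Its signal was -8.17 ± 22.9 (SD, n = 4) in NS5 cells and 68.0 ± 18.5 in astrocytes, above background on the 4 astrocyte arrays alone. Klf2 had 1.30 ± 0.40, Klf4 -0.65 ± 0.21 with 2 of the 4 astrocyte arrays above background, and Esrrb was at least 1.28-fold lower. Among endothelial markers, 4 were measured, too few for a list test, and 0 rose and 3 fell: Emcn had -1.39 ± 0.15 with 1 of the 4 astrocyte arrays above background, Egfl7 -0.81 ± 0.08 and Ramp2 -0.56 ± 0.19. Klf2 lost its call in 1 of 19 alternatives, the trend and robust prior, at an unchanged 1.30 (adjusted p = 0.0686, lowest 1.08e-04). Ramp2 lost its call in 7 of 19 (adjusted p from 6.31e-05 to 0.0697 over the 19). Its values there were -0.65 in the authors' value table and with the positive floor in place of the offset. They were -0.55, -0.56 and -0.54 without NS5 array 1, 2 or 3, and -0.40 and -0.48 without astrocyte array 1 or 3. Klf4 lost its call in 4 of 18 (adjusted p from 6.15e-04 to 0.215 over the 18). Its values there were -4.29 with the positive floor, -1.80 in the authors' value table, -0.61 without NS5 array 1 and -0.55 without astrocyte array 2. The size of the change of Klf4 is therefore not settled.

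**Figure D2:**
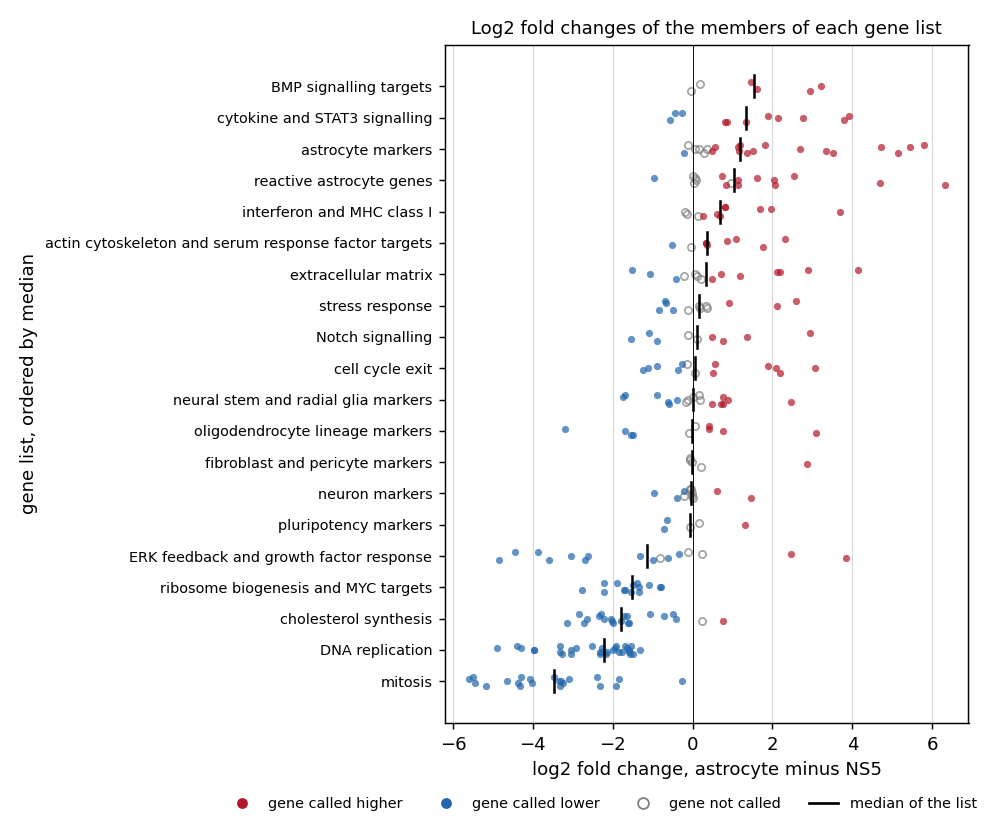
Log2 fold change, astrocyte minus NS5 (horizontal axis), of each measured member of the 20 gene lists that were tested (vertical axis, ordered by median). Red points are genes called higher, blue points genes called lower, open grey points genes not called, and black bars list medians, which ran from -3.48 for mitosis to 1.55 for BMP targets.

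Over the 20 lists tested of 22 fixed, camera called 11, 6 higher and 5 lower, and 2 of them held with an estimated correlation. Fry, which asks whether the members of a list move one way without comparing them with other genes, called 18, and 20 when either direction counted. Only the astrocyte markers changed their counts when adjusted over the list alone. With genes below background in a group set to their bound, the median of the reactive astrocyte list moved from 1.05 to 0.79, that of extracellular matrix from 0.34 to 0.17 and that of the ERK list from -1.14 to -1.07, and 17 medians did not move. The medians of the 11 called lists kept their sign over the alternatives, but 8 moved by over 1.5 times: mitosis ran from -5.87 to -3.27, replication from -3.60 to -2.14, the ERK list from -2.88 to -0.90 and BMP targets from 0.31 to 1.62. The cytokine and STAT3 list ran from 0.44 to 2.41, reactive astrocyte genes from 0.17 to 2.06, interferon and MHC class I genes from 0.28 to 1.07 and the actin list from 0.28 to 0.61. Of the 9 lists not called, 6 had medians that changed sign under at least 1 alternative, among them the neural stem and radial glia markers, from -0.10 to 0.34. Median and mean differed in sign for neuron, fibroblast and pericyte, and pluripotency markers, each of which was not called.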

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

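The gap of the highest or lowest array to its nearest neighbour, divided by the range of its group of 4, was computed for 234 groups and exceeded the 95% limit of Dixon's test in 10. Chance alone flags about 1 in 20 groups, or 11.7 of these, and no pattern was weighed. Astrocyte array 1 stood apart in 5 of the 10. On that array Mt3 was low, at a log2 value of 13.32 against 13.48 to 13.50 on the others (gap ratio 0.896). Plk1 was also low there, at 7.09 against 7.29 (0.964), Cdkn2b at 9.74 against 10.33 to 10.38 (0.933) and Ddit3 at 8.05 against 8.27 to 8.31 (0.862), while Fbl was high, at 10.53 against 10.37 to 10.39 (0.889). Astrocyte array 2 was high for Cryab, at 14.72 against 14.33 to 14.34 (0.968), and for the mean of the cholesterol synthesis list, at 9.36 against 9.24 to 9.25 (0.939). Astrocyte array 3 was low for Notch3, at 9.09 against 9.43 (0.994), and astrocyte array 4 for Jag1, at 6.66 against 6.84 to 6.88 (0.843), where the gene was not above background. NS5 array 2 was low for Acta2, at 5.93 against 6.66 to 6.71 (0.940), again below background. The calls of these 9 genes were made in every alternative in which they were tested, and that of the list in every one except the estimated correlation (adjusted p = 0.102).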

How the results depend on the processing

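The filter on the background limit and the offset of 16 were chosen after the data had been seen, and the other settings before. Over the alternatives the number of called genes ran from 4246, with the filter at the 75th percentile, where 5505 genes were tested, to 6392 with array weights, or 7235 of 12306 when all probes were counted. Leaving out 1 array gave 5809 to 6182 calls and 1893 to 1957 with at least 2-fold change. The authors' value table gave 2904 genes with at least 2-fold change against 1924, while its number of called genes was 5946. Its floor of 10 lies far below the added 99.01, which by construction widens the folds of dim genes, and the added offset of 16 gave 2645. With the mean of all probes of a gene 2 calls turned direction, and without astrocyte array 1, 2 or 3, 1 call each did. For the 92 named genes, 1696 of 1711 comparisons kept direction and call, 13 lost a call, 2 gained one and 0 reversed. The changes concerned Ramp2, Klf4, Klf2, Gad1 and S100b. With the positive floor in place of the offset of 99.01 some folds were over 1.5 times as large, with -1.71 for Dlx2, -2.95 for Emcn, -1.24 for Egfl7, -1.69 for Trib3, -1.68 for Dll1, -1.89 for Nrarp, 1.79 for Ddit3, 3.15 for Irf9, 4.30 for Junb and 5.89 for Socs3. For the medians of the 20 lists, 363 of 371 comparisons kept direction and call, 6 lost a call and 2 gained one. The actin and serum response factor list (main median 0.37) lost its call with the positive floor in place of the offset (0.38), median centring (0.35), no filter (0.28) and the filter at the 75th percentile (0.33). Leaving out 1 array gave it a median of 0.29 to 0.46, and it lost its call without astrocyte array 1 or 2. The extracellular matrix list gained a call with the positive floor in place of the offset (1.97) and with median centring (0.34), while its median ran from 0.08 with no filter to 2.11 with the filter at the 75th percentile, neither of which called it. With an estimated correlation 2 lists were called in place of 11. The cause of these list changes was not tested. The replicate numbers shared by the groups were not shown to pair the arrays over all genes tested. Deviations from the group means of arrays with the same number correlated at -0.05, 0.05, 0.15 and 0.07, and 3 of 8 arrays had their best partner under their own number. With the replicate block, 6074 genes were called, 1924 with at least 2-fold change. A block for chip or slide was not run, since none is named in the files used. Signal over background limits the dim genes, because 46.0% to 47.9% of probes on an array exceeded the estimated limit.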

Other observations

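The gene families in this and the next paragraph were defined by symbol after the data had been seen, 12 in all, and 2 of the weighed tests further on, those on cycling NS5 cells and on normalization, were also chosen afterwards. Families of ribosomal proteins, aminoacyl-tRNA synthetases and proteasome subunits were called lower in astrocytes by camera, and none of them with an estimated correlation. Of 49 cytosolic ribosomal proteins, 47 fell and 0 rose, with a median log2 fold change of -0.83 (camera adjusted p = 3.40e-12, or 0.143 with an estimated correlation). Mitochondrial ribosomal proteins fell in 51 of 68 cases and rose in 3, with a median of -0.41 (adjusted p = 6.06e-07, or 0.221), aminoacyl-tRNA synthetases fell in 15 of 22 and rose in 1, with -0.52 (4.79e-04, or 0.0508), and proteasome subunits fell in 28 of 35 and rose in 1, with -0.35 (2.60e-04, or 0.127). Complement components and regulators rose in 7 of 8 measured cases, with a median of 1.30 (4.79e-04, or 0.0508), and beside C3 and Cd59a they included Cd59b, at least 9.93-fold higher, and the inhibitor Serping1, at least 2.50-fold higher. C3, Cd59a, Cd59b and Serping1 were not above background on any NS5 array and passed the filter through their astrocyte signals. The complement genes C1qa, C1qb and C1qc were not above background on any array and are not counted, so the count does not cover the whole family. Lysosomal cathepsins rose in 4 of 8 cases (0.0432, or 0.143), among them Ctsb, from a signal of 4373 ± 303 (SD, n = 4) to 29856 ± 1702, and Ctsd, from 992 ± 109 to 3637 ± 348. The metallothionein Mt1 rose from 8831 ± 320 to 54438 ± 4808, and its family with glutathione S-transferases rose in 8 of 15 cases and fell in 4 (0.199). The medians of these 7 families kept their sign under 4 other scalings, but some sizes did not hold: that of complement genes ran from 1.27 to 3.09, that of cathepsins from 0.39 to 0.94 and that of the metallothionein and glutathione S-transferase family from 0.33 to 0.68. High mobility group proteins (0 rose, 3 fell of 7, adjusted p = 0.0820), serine protease inhibitors (3 and 2 of 13, 0.456), integrins (3 and 1 of 10, 0.462) and complex I (8 and 4 of 30, 0.430) were not called, and the median of complex I changed sign with median centring, from 0.05 to -0.08.

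The signals of replication-dependent histone genes split by class on these arrays. As a family of 36 genes, 20 rose and 9 fell, with a median log2 fold change of 0.73 but a mean of 0.02 (camera adjusted p = 0.0432, direction up, or 0.515 with an estimated correlation). Of 10 H2A genes, 8 fell and 2 rose, with a median log2 fold change of -3.70, while 11 of 12 H2B genes rose and 0 fell, with a median of 1.41, and 6 of 8 H4 genes rose and 1 fell, with 1.61. The 4 H3 genes gave 0 calls, and of 2 H1 genes 1 rose. Among the H2A genes that fell was H2ac13, from a mean signal of 36623 to 1383, whereas H2ac19 went from 673 to 6953 and H2bc4 from 3679 to 10805. The counts of risers and fallers in these classes were the same under the 4 other scalings, and the median of H3 changed sign with median centring. How far the probes of each class tell similar gene copies apart was not tested. It was also not tested how evenly the RNA amplification captured histone transcripts, so the split may not reflect their total amounts. No explanation was tested.

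Immediate-early and related genes, chosen after their values were seen, varied widely between replicates. For the 8 genes Fos, Egr1, Socs3, Junb, Klf2, Ier3, Atf3 and Ccn1 the pooled SD lay at or above the 99.3 percentile of all genes tested. Astrocyte array 3 had the highest signal for 8 of them and astrocyte array 4 the lowest for 7. Among the NS5 arrays, array 3 was highest for Fos, Egr1, Junb, Ier3 and Ccn1, and array 4 for Socs3, Klf2 and Atf3. Ccn1 and Atf3 were not above background on any NS5 array. Whether arrays of the same number share a source of this variation was not tested. Egr1, for example, ranged from 727 to 10733 over the astrocyte arrays and from 1649 to 8487 over the NS5 arrays.

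The number of called genes was set against other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 6138 genes. The highest of the others gave 0 with limma at an adjusted p under 0.05, and at most 757 at an unadjusted p under 0.05 against 6441. Chance assignment of the arrays can be excluded only at 1 of 35, the smallest share these splits allow, and the low counts of the others carry no further weight, since mixed splits hold the difference between the groups in their residual spread.

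Stem cell markers were not called as a list (median log2 fold change 0.02) while mitosis genes fell. Cycling NS5 cells left among the astrocytes would keep both alike. The percent of the NS5 signal kept in astrocytes was taken over genes above background on all 4 NS5 arrays, which left out Prom1, a stem marker that was not above background there and was higher in astrocytes. The 75th percentile of 21 mitosis genes was 2.66%, below the 25th percentile of 16 stem markers, 56.1%, with medians of 1.05% and 100.01%. These percents re-express the signals that showed the pattern, so their order was no independent test. Their size shows only that cells cycling as NS5 cells do could bring little of the signal of most of these markers. Undifferentiated cells that had left the cell cycle remain possible, and expression of these markers by the astrocytes themselves is a hypothesis that was not tested.

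In cells given serum, 19 of 21 measured cholesterol synthesis genes fell and 1 rose, Hsd17b7, named after its values were seen. Fdft1, not counted because it did not pass the filter, was above background in astrocytes alone. The call of the list was lost with an estimated correlation (adjusted p = 0.102). The median of the list kept at least 102.7% of its size under median centring and in the authors' value table. The choice among these scalings therefore did not make the fall. All of them give the arrays a common centre, so a shift of most genes between the groups could not be tested. A candidate explanation is sterol taken up from serum, which would also raise targets of the sterol-activated receptor LXR. Of 6 such targets, 2 were measured, and 2 were called higher, Lpcat3 at 0.94 and Pltp at 0.71, too few to decide. Growth factor withdrawal and serum were changed together, so their effects cannot be told apart here.

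The acute-phase genes C3, Lcn2 and Serpina3n rose strongly, and microglia or macrophages in the astrocyte cultures could bring such transcripts. Of 12 markers of microglia or macrophages on the array, 0 were above the background limit on all 4 astrocyte arrays and higher there than in NS5 cells, and the highest mean signal among them was 17.3 against a mean limit of 36.7. The markers thus gave no sign of those cells, which cultures derived from a neural stem cell line were not expected to hold. They were not above background on any NS5 array either, so no array here shows that the probes detect such cells. The response of the astrocytes to serum or to growth factor withdrawal stays open and was not tested.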
